A study of Mus musculus with 3 samples.

How the data were processed

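Nuclei of mouse lacrimal gland were profiled by droplet single-nucleus RNA sequencing (10x Genomics 3' v3 chemistry, per the labels). The series holds 3 libraries, 1 per group: a control gland, a gland of the dry eye model made with scopolamine and dry stress, and a gland of the same model given tamsulosin. Scopolamine blocks muscarinic receptors, and tamsulosin blocks alpha-1 adrenergic receptors. The libraries are called control, scopolamine and tamsulosin here. The number of animals behind each library is not stated, so each group counts as n = 1. The labels also mention a sort of fluorescent nuclei and a plate method in a protocol text that covers several assays, and whether the sort applies to these libraries could not be settled.

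The authors deposited raw UMI counts per gene and barcode, made with Cell Ranger 5.0.0 on the mouse genome mm10, per the file headers and the labels. The deposited gene and barcode lists name the 32285 genes and the barcodes of these matrices and carry no other measured value. The annotation release, the counting of intronic reads and further filters were not stated. The deposited barcodes number 7253 for control, 10024 for scopolamine and 12322 for tamsulosin, and their lowest UMI totals are 1492, 967 and 1534, so shallower droplets had been left out before deposit. Without the empty droplets, free RNA could not be estimated directly or removed.

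Nuclei with at least 500 UMIs, at least 300 detected genes and at most 5% mitochondrial UMIs were taken further. Scrublet (in scanpy 1.11.5, expected rate 0.06) was run on each library. It marked fewer than 0.5% of each library, so by the rule fixed beforehand the highest scores were removed at 0.8% per 1000 nuclei, which took out 414, 801 and 1156 nuclei. The mitochondrial limit removed 59, 16 and 271 barcodes, and the gene minimum 0, 2 and 31. This left 6780, 9205 and 10864 nuclei, 26849 in all. Counts were scaled to a fixed total per nucleus and log-transformed, 2000 variable genes were chosen across libraries, and 30 principal components with 15 exact neighbours gave 25 Leiden clusters at resolution 1.0 (igraph 0.11.9). No integration was applied. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

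Clusters were named from marker lists written before the data were examined. The thresholds of the naming rule were set and revised several times after the clusters had been seen. In its final form, each marker's CPM in a cluster was set against the median over clusters on the log2 scale. A class other than acinar or duct needed a mean of at least 2 over its markers, with at least 3 markers at 1 or more and seen in a share of at least 0.2 of the nuclei. Duct needed a mean of at least 0.4 with at least 5 markers at 1 or more, in any share of the nuclei, a weaker criterion than for those classes. Clusters not named in this way, and with a median of at least 350 genes at 1000 UMIs, were named acinar where at least 3 acinar markers were at least 1.25-fold above the nuclei of the same libraries in named classes other than duct, salivary and erythroid, a weak criterion that makes acinar-like partly a remainder class. Those below 350 genes were left unnamed as low-complexity nuclei. All names rest on transcripts alone and are written with "-like". The acinar-like class had the most epithelial nuclei and was the main class. A class was compared where it had at least 100 nuclei in each library, which held for acinar-, duct-, myoepithelial-, fibroblast-, macrophage- and T or NK-like nuclei.

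Shares of nuclei carry exact Clopper-Pearson 95% intervals. UMIs were summed per library and class and given as CPM, the UMIs of a gene scaled to a total of 1e6 UMIs with exact Poisson intervals. Ratios of CPM carry the exact conditional binomial 95% interval. A gene with no UMIs was set against a floor of 3 counts. These intervals cover counting error only, since UMIs from 1 library say nothing about differences between animals. With 1 library per group no test between groups was possible, no p-value is given and no genes are called changed. No paired analysis was possible either. Log2 ratios used a pseudocount of 5 CPM. In each class the median log2 ratio over genes at a mean of at least 20 CPM was subtracted to give relative ratios. In acinar-like nuclei it was -0.25 for scopolamine against control, -0.09 for tamsulosin against scopolamine and -0.33 for tamsulosin against control, over 5723 genes.

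The named genes were chosen by a rule fixed before the data were examined: in acinar-like nuclei the 10 highest and 10 lowest log2 ratios among genes at a mean of at least 20 CPM, and in each other class the 3 highest and 3 lowest with at least 50 CPM and 30 UMIs in the higher library. In the higher library the CPM had to reach that of all other nuclei. Of the genes this rule names in duct-like nuclei, 1 is not reported. Unnamed gene models and mitochondrial, ribosomal, hemoglobin, immunoglobulin and sex genes were left out of this choice. The lists of gene groups were fixed beforehand too. For each, the median relative log2 ratio was taken over members with at least 20 UMIs, members at least 1.5-fold higher or lower after the median shift were counted by size, and the median was placed among 10000 random lists of equal size matched on CPM in 20 bins. From each list up to 4 members with the largest ratios are given as examples. The symbols Lacrt, Mx1, Mx2 and Spink3 were not in the files. Markers of other cell types in acinar-like nuclei were measured in the same way, without random lists, after list values had been seen. The number of lists outside the central 95% of random lists was taken as a summary after list values had been seen. The distance between libraries is the median absolute log2 ratio over genes at 20 CPM. The position of the tamsulosin library is the median of its log2 distance from control over that of the scopolamine library, over genes at least 2-fold apart in 1 part of the nuclei and measured in the other, in 20 random divisions.

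Gene positions came from GENCODE M21 on GRCm38, the assembly called mm10, matched by Ensembl identifier for 161 of 161 genes. Gene lengths were available for 32235 of 32285 genes. The procedure was tested on simulated data with 5745 genes, of which 100 were set to 2-fold and 100 to 0.5-fold. For scopolamine against control the median recovered folds were 1.998 and 0.501, with the right direction in 100% of changed genes. The ratio intervals covered the true value for 94.9, 95.4 and 95.5% of genes in the 3 comparisons, and of 100 unchanged lists 3, 2 and 3% fell outside the central range. The simulated lists were random draws of genes with independent counts, so a low share outside was set by the design. It says nothing about lists whose genes vary together, as real lists can.

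The alternatives fixed beforehand were doublets kept, at least 1000 UMIs and 500 genes, Leiden resolutions 0.5 and 2.0, genes centred within each library, median-of-ratios scaling, totals without the 50 most abundant genes, nuclei thinned to 1000 UMIs, a pseudocount of 1, gene minimums of 5 and 50 CPM, and list members with at least 100 UMIs. After the data had been seen, 4 were added: acinar-like nuclei without clusters 0, 19 and 22, which share Kit, Car6 and Zfp385b among their top genes, at least 1600 UMIs in every library, low-complexity clusters counted as acinar-like, and random lists matched on gene length too.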

Results

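The data describe 3 libraries of mouse lacrimal gland nuclei, 1 per group, so no value has a replicate. After filtering, the control library held 6780 nuclei with a median of 2318 UMIs, the scopolamine library 9205 with 1732 and the tamsulosin library 10864 with 3361. Total UMIs over all deposited barcodes were 33500727, 35237256 and 57969348. The lowest UMI total of a deposited barcode was 1492, 967 and 1534. At 1000 UMIs per nucleus the median number of detected genes was 687, 538 and 507, and the median mitochondrial share was 0.118, 0.269 and 0.754%. All intervals are 95% intervals for counting error only.

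Acinar-like nuclei are partly a remainder class, named after the secretory cells of the gland. They made up 77.7% (76.6 to 78.6) of control nuclei, 67.6% (66.6 to 68.5) of scopolamine nuclei and 21.6% (20.9 to 22.4) of tamsulosin nuclei. Duct-like nuclei made up 5.83% (5.28 to 6.41), 7.29% (6.77 to 7.84) and 31.6% (30.7 to 32.4). Macrophage-like nuclei made up 4.66% (4.17 to 5.19), 6.39% (5.90 to 6.91) and 4.22% (3.85 to 4.62). Myoepithelial-like nuclei, the contractile cells around the acini, were 3.67, 4.27 and 3.001%, fibroblast-like nuclei 3.61, 3.93 and 2.75%, and T or NK-like nuclei 1.58, 2.07 and 1.93%. Nuclei left unnamed for low complexity took 0.693, 5.78 and 29.9%. Of the 3248 such tamsulosin nuclei, 2808 lay in cluster 17, with a median of 331.5 genes at 1000 UMIs. That is close to the limit of 350, which was set after the clusters had been seen. The naming rule counted 19 acinar markers in cluster 17, against 11 to 21 in the acinar-like clusters. The tamsulosin acinar-like share of 21.6% therefore depends on this limit. In tamsulosin low-complexity nuclei the nuclear retained Malat1 took 0.744% of UMIs, against 2.75% in acinar-like nuclei. Mucl2, Scgb2b2 and Scgb1b2 together took 42.0%, against 14.7%. Chrm3 lay at 653 CPM, against 3336 in acinar-like and 1151 in macrophage-like nuclei. Whether these barcodes hold acinar nuclei or mostly free RNA was not tested, and a count of acinar markers does not decide it.

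The libraries filled different clusters within a class. Of the acinar-like clusters, cluster 4 held 3680 control, 28 scopolamine and 0 tamsulosin nuclei, cluster 21 held 8, 3794 and 24, and cluster 24 held 0, 123 and 1462. The mean log2 ratio of all acinar markers to the reference nuclei of the naming rule was below 0 in some acinar-like clusters. It was -0.35, -0.261, -0.271 and -0.00656 in clusters 2, 12, 20 and 24, and 0.054 to 0.827 in the other acinar-like clusters. Clusters 0, 19 and 22, which share Kit, Car6 and Zfp385b among their top genes, together held 8.43, 6.85 and 27.7% of the acinar-like nuclei. They numbered 444, 426 and 650 of 6780, 9205 and 10864 kept nuclei, so the 27.7% reflects the low number of acinar-like nuclei in that library. Of the duct-like clusters, cluster 8 held 357, 1 and 0 nuclei and cluster 16 held 14, 319 and 2799. Duct-like clusters 8, 14, 16 and 18 each had 0 duct markers among their 10 top genes. Their mean log2 values over the duct markers were 0.723, 1.17, 0.8 and 0.475, so the duct-like name rests on a weak criterion too. Counting low-complexity clusters as acinar-like, chosen after seeing the data, put the acinar-like share of the tamsulosin library at 51.5%. With at least 1000 UMIs and 500 genes that share was 45.6% and the control duct-like share 0.457%. In that setting a cluster of 415 control, 2 scopolamine and 0 tamsulosin nuclei was named acinar-like. Whether it holds the nuclei of duct-like cluster 8 was not tested, so the 0.457% may reflect naming. The 45.6% holds 1927 nuclei of a cluster whose 10 top genes have 1 acinar marker and 3 markers of another class, and the share was 25.6% without it. At Leiden resolution 2.0 the tamsulosin duct-like share was 31.8%, and 21.1% without 2 clusters with more top markers of another class, and with at least 1600 UMIs in every library the scopolamine duct-like share was 12.2%.

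**Figure D1:**
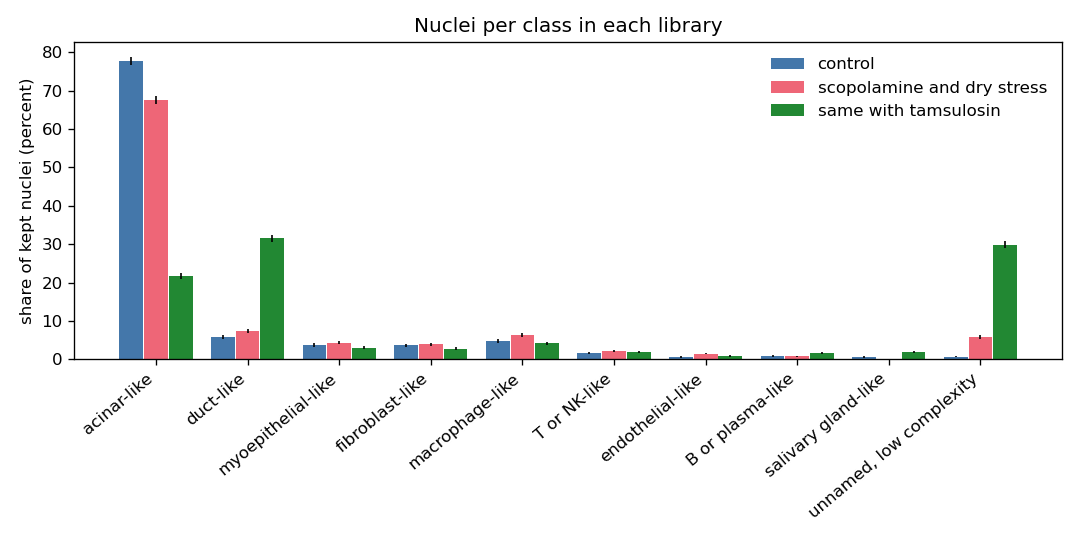
Share of kept nuclei in percent (vertical axis, from 0) for 10 classes in the control, scopolamine and tamsulosin libraries, with bars for the share and error bars for the exact binomial 95% interval. The acinar-like share is lowest in the tamsulosin library, at 21.6%, and its low-complexity share is 29.9%.

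The comparison of the scopolamine library with control asks how the dry eye model differs from the normal gland. In acinar-like nuclei Pnliprp1, a pancreatic lipase-related gene, was 23.2-fold lower (21.9 to 24.5), at 1437 CPM in control and 62.0 in scopolamine. Lipo1, of the lipase family, was 11.9-fold higher (10.5 to 13.5), at 11.4 and 135 CPM, and Esp16, an exocrine gland-secreted peptide, 7.19-fold higher (6.87 to 7.53), at 84.7 and 609 CPM. Asns, the asparagine synthetase, was 4.72-fold lower (4.15 to 5.38) and Aldh1l2, a mitochondrial folate enzyme, 5.89-fold lower (5.24 to 6.63). The core clock activator Arntl was 3.47-fold higher (3.23 to 3.72), and the clock repressor Nr1d2 3.51-fold lower (3.32 to 3.72).

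The other genes named as higher were Ptprt (5.09-fold), Insyn2a (5.09-fold), Pard3bos1 (4.89-fold), Sorbs2os (4.51-fold), Pdlim3 (4.44-fold), Plet1os (4.11-fold) and Nrg4 (3.31-fold), a ligand of the ERBB receptors. The others named as lower were Ttc7b (6.09-fold), Cyp2a5 (5.83-fold), Taco1 (5.14-fold), Slc6a9 (4.85-fold), a glycine transporter, Trim24 (3.73-fold) and Phyh (3.34-fold), a peroxisomal enzyme. Pnliprp1 (ENSMUSG00000042179) lies on chromosome 19 from 58728887 to 58744169 of mm10, and Lipo1 (ENSMUSG00000079342) on chromosome 19 from 33775498 to 33787459. Esp16 (ENSMUSG00000096345) lies on chromosome 17 from 39536142 to 39540847, and Cyp2a5 (ENSMUSG00000005547) on chromosome 7 from 26835305 to 26843548. Arntl (ENSMUSG00000055116) lies on chromosome 7 from 113207465 to 113314126, and Nr1d2 (ENSMUSG00000021775) on chromosome 14 from 18204054 to 18239127.

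Across acinar-like genes in this comparison 9.96% were at least 1.5-fold higher and 1.71% at least 1.5-fold lower relative to the class median. Of the 29 gene lists, 15 had a median above and 1 a median below the central 95% of random lists. Members of a list are counted as higher or lower at 1.5-fold after a pseudocount of 5 CPM and relative to the class median. In the tear and secretory list, 10 of 18 measured members were at least 1.5-fold higher and 1 lower, with a relative median log2 of 0.63 (percentile 100). Examples are Obp1a at 14735 and 48414 CPM, Scgb2b24 at 2617 and 8614 CPM and Pip at 1181 and 3332 CPM. The secretory list took 3.02% of UMIs in control and 7.20% in scopolamine acinar-like nuclei, and 2.91 and 6.39% in macrophage-like nuclei. Those should lack most of these transcripts, apart from Lyz2, which is also a macrophage marker. T or NK-like nuclei had 3.22 and 7.98% and myoepithelial-like nuclei 3.82 and 9.42%, above the acinar-like shares. Duct-like nuclei had 2.01 and 5.38% and fibroblast-like nuclei 2.59 and 6.29%, below them. The ion and water transport list had a median of 0.50 (percentile 100), with 6 of 19 members higher, among them the potassium channel gene Kcnn4 at 38.1 and 88.2 CPM.

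Among inflammatory lists, 9 of 19 NF-kB and acute phase members were higher (median 0.58, percentile 100), including Cxcl1 at 1.53 and 13.3 CPM and Tnf at 1.73 and 7.75 CPM. In the interferon list 12 of 22 were higher (0.59, percentile 100), including Ifi44 at 3.70 and 12.7 CPM. Chemokines had 5 of 11 higher (0.56, percentile 100) and immediate early genes 4 of 15 (0.48, percentile 99.8). The matrix list had 11 of 26 higher (0.51, percentile 100), among them Fbn1 at 4.49 and 11.3 CPM in acinar-like and 111 and 318 CPM in fibroblast-like nuclei. Markers of other cell types were also higher in acinar-like nuclei relative to the class median, with relative medians of 0.59 for 11 fibroblast, 0.57 for 8 myoepithelial, 0.51 for 11 endothelial, 0.40 for 14 macrophage and 0.38 for 9 T or NK markers. At least 1.5-fold higher were 6, 4, 2, 3 and 0 of them, and 1 endothelial and 1 macrophage marker was lower. For markers with few UMIs the pseudocount holds the log2 ratio near 0, so subtracting the class median of -0.25 raises these values. No random lists were drawn for the markers. Progenitor genes had 6 of 19 higher (0.40, percentile 99.8), with Clu at 3.46 and 19.4 CPM, and apoptosis and p53 genes 4 of 21 (0.42, percentile 99.8). Glucocorticoid response had 2 of 12 higher (0.43, percentile 99.7), epithelial junctions 4 of 17 (0.25, percentile 98.4) and androgen response 6 of 14 (0.28, percentile 99.5).

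Ribosomal protein genes had 16 of 26 members higher (0.68, percentile 100), mitochondrially encoded genes 8 of 13 (0.73, percentile 100) and nuclear retained RNA 2 of 7 (0.47, percentile 99.4). The median of the circadian clock list lay below the central range, at -0.11 (percentile 0.29), with 4 of 18 members higher and 5 lower, and it came to percentile 25.3 in thinned nuclei and 5.55 with members of at least 100 UMIs. Inside the central range, the unfolded protein response list had 3 of 24 members higher and 3 lower (0.03, percentile 32.9), the latter being Asns at 63.1 and 13.4 CPM, Atf6 at 366 and 165 CPM and Herpud1 at 333 and 150 CPM. Lipid metabolism had 8 of 30 higher and 1 lower (0.19, percentile 65.4), oxidative stress defence 2 of 24 higher and 2 lower (0.15, percentile 66.6) and MAPK and growth factors 4 of 27 higher and 1 lower (0.22, percentile 94.6). Antigen presentation had 4 of 15 higher (0.40, percentile 96.8). Heat shock had 1 of 11 higher and 1 lower (0.18, percentile 74.4), glycolysis 1 of 20 higher and 1 lower (0.15, percentile 22.7), autophagy 3 of 22 higher (0.09, percentile 77.2), exocytosis 1 of 17 higher (0.20, percentile 87.9) and nuclear encoded oxidative phosphorylation 4 of 42 higher (0.20, percentile 95.7). Of these lists, 3 went above the range under other settings. Antigen presentation came to percentiles of 97.75 to 99.8 under 4 of them, MAPK to 98.75 thinned and 98.0 with doublets kept, and oxidative phosphorylation to 99.85 and 97.9 in the same 2. No member was counted among 24 calcium signalling genes (0.11, percentile 72.7), 20 mitochondrial dynamics genes (-0.09, percentile 4.33) and 6 receptor genes (0.16, percentile 39.8). As plain CPM ratios with an interval beyond 1, these 3 lists had 1, 0 and 1 members at least 1.5-fold higher and 3, 4 and 2 lower, among the latter Adra1a (1.68-fold), Adrb1 (2.87-fold), Sirt3 (1.80-fold) and Orai1 (1.63-fold). Counted so, the clock list had 4 higher and 10 lower, progenitor genes 10 higher and 5 lower, NF-kB 15 higher and matrix 15 higher.

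With random lists matched on gene length too, 13 of the 29 lists fell outside the central range, and the mitochondrially encoded list came to percentile 76.1, androgen response to percentile 52.1 and nuclear retained RNA to percentile 95.7. With members of at least 100 UMIs 12 lists fell outside, and apoptosis genes came to percentile 75.4, glucocorticoid response to 81.3, progenitor genes to 90.9 and junctions to 96.4. Thinned, apoptosis genes came to percentile 73.65 and glucocorticoid response to 91.6. With doublets kept, progenitor genes came to 97.4 and nuclear retained RNA to 95.95, and junctions came to 95.5 without the 50 most abundant genes and 96.25 without clusters 0, 19 and 22. With at least 1600 UMIs in every library, immediate early genes came to percentile 96.4, progenitor genes to 96.75 and junctions to 97.05, and the mitochondrially encoded list turned from above to below the range, at percentile 0.30. Before the class median is subtracted, the list medians of ribosomal and mitochondrially encoded genes changed sign with at least 1600 UMIs in every library, those of apoptosis and glucocorticoid genes with nuclei thinned to 1000 UMIs and with members of at least 100 UMIs, and that of junction genes with both of these and Leiden resolution 2.0.

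**Figure D2:**
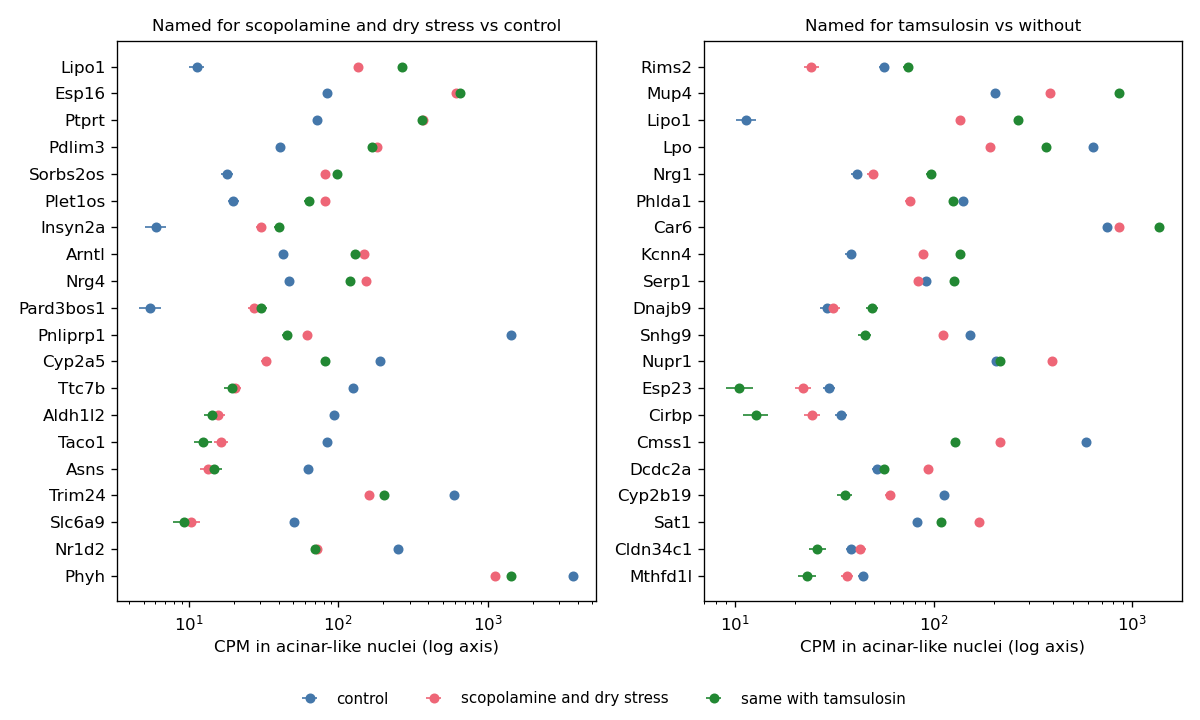
CPM (log axis) in acinar-like nuclei of the 20 genes named for scopolamine against control and of the 20 named for tamsulosin against scopolamine, with points for each library and bars for the exact Poisson 95% interval. In the left panel the tamsulosin points lie near the scopolamine points for most genes, with Pnliprp1 at 1437, 62.0 and 45.6 CPM.

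Clock genes outside acinar-like nuclei were examined after their values in that class had been seen. Relative to the class median, the log2 ratio of Arntl was 1.93 in acinar-, 1.51 in duct-, 2.62 in myoepithelial-, 1.92 in fibroblast-, 1.85 in macrophage- and 0.58 in T or NK-like nuclei. For Nr1d2 the values were -1.50, -1.04, -2.00, -2.01, -2.05 and -1.45 in the same order. Npas2, a partner of the same kind as Clock, had values from 0.68 in myoepithelial-like to 3.73 in fibroblast-like nuclei. Tef, a clock output gene, lay between -1.08 in T or NK-like and -1.59 in fibroblast-like nuclei.

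**Figure D3:**
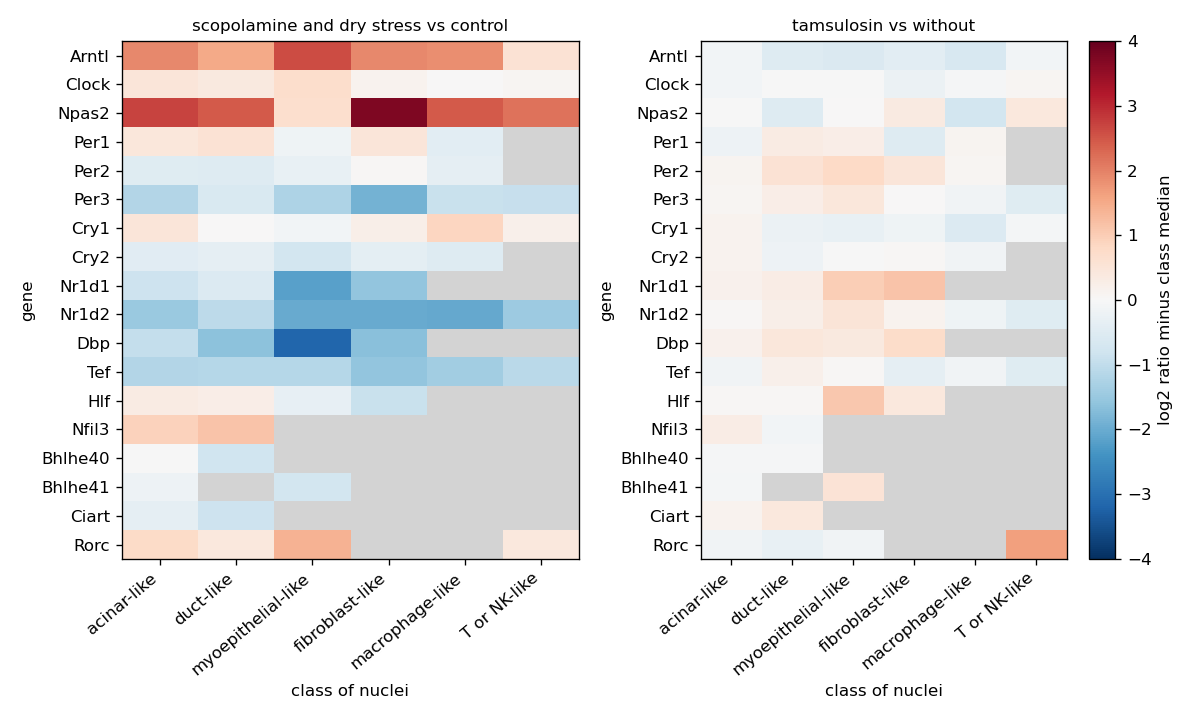
Log2 ratio minus the class median (colour) for the 18 genes of the clock list (vertical) in 6 classes of nuclei (horizontal), for scopolamine against control (left) and tamsulosin against scopolamine (right); grey marks genes with too few UMIs. In the left panel Arntl is higher and Nr1d2 lower in every class, with Npas2 at 3.73 in fibroblast-like nuclei.

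In the other classes, duct-like nuclei had Npas2 5.73-fold higher (4.07 to 8.27), Cp, the ceruloplasmin gene, 4.08-fold higher (3.41 to 4.90) and Sult1e1, an estrogen sulfotransferase, 4.08-fold higher (3.38 to 4.96). Tef was 2.55-fold lower there and Dmbt1 2.34-fold. With at least 1600 UMIs in every library the log2 ratio of Dmbt1 went from -1.23 to -0.57, of Cp from 1.96 to 2.67 and of Sult1e1 from 1.96 to 2.63. Myoepithelial-like nuclei had Dbp, a clock output gene, 91.9-fold lower (15.9 to 3690), Nr1d2 5.39-fold and Lars2 4.84-fold lower, and Scgb1b2 5.41-fold, Scgb2b24 4.14-fold and Scgb2b2 3.35-fold higher. With doublets kept the Dbp log2 ratio went from -3.50 to -2.79. Scgb1b2, Scgb2b2 and Mucl2 together took 3.70% of macrophage UMIs in control and 11.9% in scopolamine. Fibroblast-like nuclei had Dgkb 39.6-fold (20.6 to 87.1), Ctnna3 32.5-fold and Kcnab1 31.8-fold higher, and Taco1 7.71-fold, Fgg 6.56-fold and Nr1d2 4.98-fold lower. Taco1 was also named as lower in acinar-like nuclei and is a top gene of acinar-like cluster 2, so free RNA cannot be told apart for it. A cluster of pericyte or vascular smooth muscle-like nuclei, with 0 control, 16 scopolamine and 3 tamsulosin nuclei, lay apart with doublets kept and with at least 1000 UMIs and 500 genes, but not in the clusters used here. The log2 ratios of Dgkb, Ctnna3 and Kcnab1, at 4.62, 4.34 and 4.36, came to 0.45, 0.90 and 1.03 under the first of these settings and to -0.0023, 0.36 and 0.96 under the second. They were 0.29, 1.20 and 1.503 at Leiden resolution 2.0 and 1.22, 1.23 and 1.91 with at least 1600 UMIs. Thinned, Dgkb came to 3.88 and Ctnna3 to 3.20, Taco1 went from -2.49 to -3.26 and Fgg from -2.22 to -1.51.

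Macrophage-like nuclei had Insyn2b 9.61-fold (4.23 to 27.0), Adap2os 6.60-fold and Scgb2b20 4.70-fold higher, and Rab6b 4.15-fold, Siglech 3.21-fold and Lars2 3.10-fold lower. T or NK-like nuclei had Lipo1 17.2-fold (4.51 to 146), Oprm1 6.11-fold and Cd244a 3.67-fold higher, and Rims2 4.85-fold, Farp2 4.18-fold and Dmbt1 3.75-fold lower. Lipo1 and Rims2 are also named genes of acinar-like nuclei, and Dmbt1 is a top gene of duct-like cluster 8. For these 3 genes free RNA from epithelial nuclei cannot be told apart from expression within T or NK-like nuclei. Scgb2b20 and Lars2 are likewise top genes of low-complexity cluster 23 and acinar-like cluster 4. The log2 ratio of Cd244a went from 1.73 to 2.55 and of Oprm1 from 2.35 to 2.93 with at least 1600 UMIs in every library. Thinned, that of Dmbt1 went from -1.84 to -1.13, of Farp2 from -1.93 to -2.54 and of Adap2os from 2.35 to 1.64. The matrix list in fibroblast-like nuclei had 14 of 22 members higher and 1 lower (relative median 0.68, percentile 100), with Fbn1 at 111 and 318 CPM, but with at least 1000 UMIs and 500 genes its median before the shift was -0.25 (percentile 2.80). In macrophage-like nuclei 4 of 8 chemokines (0.61, percentile 99.1) and 4 of 15 antigen presentation genes (0.45, percentile 100) were higher, among the latter Cd74 at 127 and 186 CPM.

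The comparison of the tamsulosin with the scopolamine library asks how the treated model differs from the untreated one. In acinar-like nuclei Rims2, a gene of vesicle release, was 3.07-fold higher (2.76 to 3.42), at 24.2 CPM in scopolamine and 74.3 in tamsulosin, against 56.0 in control. Lpo, the lactoperoxidase gene, was 1.91-fold higher (1.84 to 1.99), at 192 and 367 CPM against 634 in control. Mup4, a major urinary protein of the lipocalin family, was 2.24-fold higher (2.18 to 2.30), but 1.34-fold (1.28 to 1.40) without clusters 0, 19 and 22, a setting chosen after the data were seen. These clusters have Mup4 at 4227 and 5134 CPM and make up 6.85% of scopolamine and 27.7% of tamsulosin acinar-like nuclei. They are 426 of 9205 and 650 of 10864 kept nuclei, so most of the difference in share comes from the number of acinar-like nuclei. Nupr1, a stress-response gene, was 1.84-fold lower (1.77 to 1.92), at 394 and 214 CPM against 206 in control. Snhg9, a snoRNA host transcript, was 2.49-fold lower (2.28 to 2.71), but its log2 ratio went from -1.22 to -0.37 with at least 1600 UMIs in every library.

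The others named as higher were Lipo1 (1.96-fold), Nrg1 (1.95-fold), Phlda1 (1.66-fold), Car6 (1.59-fold), a secreted carbonic anhydrase, Dnajb9 (1.56-fold) and Serp1 (1.52-fold), both of the endoplasmic reticulum, and Kcnn4 (1.54-fold). Without clusters 0, 19 and 22, where Nrg1, Car6 and Phlda1 are most abundant, Nrg1 was 1.22-fold lower (1.06 to 1.40), Car6 1.15-fold lower (1.11 to 1.18) and Phlda1 1.38-fold higher (1.27 to 1.496). The others named as lower were Esp23 (2.10-fold), Cirbp (1.92-fold), Cyp2b19 (1.68-fold), Cmss1 (1.67-fold), Dcdc2a (1.67-fold), Cldn34c1 (1.64-fold), Mthfd1l (1.59-fold) and Sat1 (1.56-fold). Rims2 (ENSMUSG00000037386) lies on chromosome 15 from 39198261 to 39684372, and Mup4 (ENSMUSG00000041333) on chromosome 4 from 59956804 to 59960710. Snhg9 (ENSMUSG00000090101) lies on chromosome 17 from 24719531 to 24719965, and Nupr1 (ENSMUSG00000030717) on chromosome 7 from 126623249 to 126630861.

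In this comparison 1.24% of acinar-like genes were at least 1.5-fold higher and 1.26% lower relative to the class median, and 9 of 29 lists lay above and 6 below the central range (7 and 3 in nuclei thinned to 1000 UMIs, 7 and 8 without clusters 0, 19 and 22). The tear and secretory list had 11 of 20 members higher (relative median 0.71, percentile 100), including Wfdc18 at 232 and 1453 CPM and Ltf, the lactoferrin gene, at 233 and 773 CPM. This list took 7.20 and 9.06% of acinar-like UMIs and 6.39 and 9.83% of macrophage-like UMIs. Bpifa2, also a salivary transcript, had 0 UMIs in all scopolamine nuclei and 172 CPM in tamsulosin acinar-like nuclei, and the tamsulosin library held 1.91% salivary-type nuclei. The unfolded protein response list had 4 of 23 higher (0.30, percentile 100), including Dnajb9 at 31.2 and 48.7, Pdia6 at 33.8 and 52.4, Hyou1 at 47.2 and 70.8 and Dnajc3 at 316 and 464 CPM. Ion and water transport had 4 of 17 higher (0.15, percentile 99.8), among them Slc12a2 at 72.3 and 121 CPM. Heat shock had none of 12 counted (0.24, percentile 100).

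Lists below the central range were NF-kB and acute phase response (-0.19, percentile 0, 1 of 19 lower, Tnf at 7.75 and 2.70 CPM), matrix (-0.21, percentile 0, 7 of 26 lower) and apoptosis and p53 (-0.14, percentile 0, 1 of 21 lower, Bcl2 at 22.5 and 8.04 CPM). Immediate early genes (-0.09, percentile 1.03, none of 14 counted), MAPK and growth factors (-0.07, percentile 1.89, 1 of 26 higher and 2 lower) and nuclear retained RNA (-0.32, percentile 0, 1 of 7 lower) lay there too. The last holds Malat1 at 37733 and 27511 CPM. In the same acinar-like nuclei markers of other cell types were lower, with relative medians of -0.32 for 11 fibroblast, -0.51 for 8 myoepithelial, -0.25 for 9 endothelial, -0.12 for 13 macrophage and -0.16 for 7 T or NK markers. At least 1.5-fold lower were 4, 4, 0, 2 and 0 of them. As plain CPM ratios with an interval beyond 1, 17 matrix, 7 NF-kB, 7 apoptosis and 4 immediate early genes were at least 1.5-fold lower and 1 NF-kB gene higher. The immediate early genes were Klf6 (1.61-fold), Junb (1.80-fold), Atf3 (2.75-fold) and Egr1 (10.5-fold). Ribosomal protein genes had 13 of 26 higher (0.58, percentile 100), mitochondrially encoded genes 11 of 13 (0.78, percentile 100), nuclear encoded oxidative phosphorylation 3 of 42 (0.26, percentile 100), antigen presentation 1 of 15 (0.19, percentile 99.8) and androgen response 1 of 14 with 1 lower (0.11, percentile 99.3).

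Inside the central range were the clock (0.03, percentile 60.3, none of 17 counted), interferon response (0.00, percentile 23.0, none of 23) and chemokines (-0.01, percentile 28.3, 1 of 9 higher). So were calcium signalling (-0.07, percentile 4.62, none of 24), exocytosis (-0.00, percentile 35.7, none of 16), mitochondrial dynamics (-0.00, percentile 34.2, none of 20), glycolysis (0.06, percentile 71.7, none of 20) and autophagy (0.01, percentile 41.8, none of 22). The rest were lipid metabolism (0.05, percentile 74.1, 1 of 30 lower), oxidative stress defence (0.08, percentile 92.2, 1 of 23 higher), glucocorticoid response (-0.07, percentile 5.70, none of 12), progenitor genes (-0.06, percentile 3.44, 1 of 19 higher and 1 lower), junctions (0.03, percentile 71.0, none of 17) and receptors (-0.05, percentile 29.1, none of 5). As plain CPM ratios the lists with none counted had up to 2 members higher and 2 lower, apart from immediate early genes. Chemokines had 1 higher and 3 lower (Cxcl1, Cxcl2 and Cxcl10), and progenitor genes 1 higher and 4 lower. With random lists matched on gene length too, androgen response came to percentile 44.4 and MAPK to percentile 9.60. Thinned, NF-kB came to percentile 13.1, apoptosis to 3.70, nuclear retained RNA to 6.85, MAPK to 40.9, antigen presentation to 78.7 and androgen response to 24.6, so these calls were lost. Without clusters 0, 19 and 22, antigen presentation came to 97.2 and androgen response to 94.4, and chemokines went below the range, at 0.40. MAPK was lost under 9 settings in all, immediate early genes with at least 1600 UMIs (percentile 16.0), and interferon response came to percentile 0.05 thinned, 2.45 with doublets kept and 99.8 with at least 1600 UMIs. With doublets kept nuclear retained RNA came to percentile 3.55. Progenitor genes lay below the range under 5 settings, at percentiles of 0.80 without clusters 0, 19 and 22, 0.20 with median-of-ratios scaling, 0.45 without the 50 most abundant genes, 0.50 with a pseudocount of 1 and 1.5 with members of at least 100 UMIs, and calcium signalling came to 2.05 without the 50 most abundant genes and 0.50 without those clusters. Before the shift, the androgen median changed sign with thinned nuclei and with doublets kept.

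In duct-like nuclei Wfdc18, a whey acidic protein family gene, was 4.82-fold higher (4.62 to 5.03) in the tamsulosin library, Tmem176a 3.96-fold (3.43 to 4.61) and Cyp2a5 3.20-fold (2.89 to 3.55). Pdzrn4 was 38.3-fold lower (27.1 to 55.4), Sult5a1 33.6-fold (22.5 to 51.6) and Trp63, a basal cell transcription factor, 14.9-fold (10.98 to 20.5). Duct-like cluster 14, which has Pdzrn4 and Sult5a1 among its top genes, held 21 control, 76 scopolamine and 22 tamsulosin nuclei, out of 395, 671 and 3428. For both genes the smaller share of this cluster in tamsulosin was not separated from lower expression within duct-like nuclei, since they were not counted inside and outside the cluster. Trp63 is a top gene of myoepithelial-like cluster 3, and a different mix of nuclei was not tested for it either. Fibroblast-like nuclei had Pcdh15 48.8-fold (16.3 to 240), Csmd1 6.75-fold and Igfbp3 4.00-fold higher, and Acta2 7.15-fold, Myom1 5.58-fold and Ryr2 5.58-fold lower, the last group being genes of muscle. With doublets kept, where 16 scopolamine and 3 tamsulosin nuclei of pericyte or vascular smooth muscle type lay apart, the log2 ratios of Acta2, Myom1 and Ryr2 went from -2.45, -2.27 and -2.27 to -0.27, -0.42 and -1.42. With at least 1000 UMIs and 500 genes they were -0.77, -0.14 and -0.30, and that of Pcdh15 went from 3.98 to 2.82. With at least 1600 UMIs they were -0.41, -0.66 and -1.66, at Leiden resolution 2.0 Acta2 and Myom1 came to -0.42 and -0.45, and with doublets kept Csmd1 went from 2.71 to 2.12. Their matrix list had 15 of 22 members higher and 1 lower (0.83, percentile 100), including Col1a1 at 46.1 and 103 CPM and Col3a1 at 417 and 715 CPM.

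Macrophage-like nuclei of the tamsulosin library had Fth1, the ferritin heavy chain gene, 2.78-fold (2.002 to 3.91), Tpt1 2.68-fold and Serp1 2.08-fold higher, and Cd36, a scavenger receptor gene, 2.81-fold (2.16 to 3.69), Colec12 2.28-fold and Ptprm 2.17-fold lower. In them 7 of 15 antigen presentation genes were higher (0.55, percentile 100), including H2-Ab1 at 107 and 217 CPM and Cd74 at 186 and 317 CPM, and 3 of 10 chemokines (0.35, percentile 95.4, or 98.65 thinned). Myoepithelial-like nuclei had Scgb2a2 2.85-fold, Fth1 2.76-fold and Tpt1 2.47-fold higher, and Trpm6 3.86-fold, Lrrc28 3.74-fold and Vps8 2.67-fold lower. With doublets kept their log2 ratios went from -1.71, -1.67 and -1.23 to 0.17, -0.45 and -0.36. Tpt1 belongs to the ribosomal list, whose share was 2.01-fold higher in macrophage-like nuclei. Fth1 and Tpt1 are top genes of low-complexity cluster 17, with 62 scopolamine and 2808 tamsulosin nuclei. T or NK-like nuclei had Jchain 13.2-fold higher (4.99 to 49.6), and Chia1 and Dcpp1, with 0 UMIs in scopolamine, at least 11.04-fold and 10.1-fold higher. In tamsulosin these stood at 131, 81.8 and 74.6 CPM in T or NK-like nuclei against 42.1, 81.3 and 28.7 CPM in all other nuclei. Chia1 is a top gene of salivary-type cluster 11, with 37 control, 0 scopolamine and 208 tamsulosin nuclei, and B or plasma-like nuclei, which express Jchain, numbered 53, 69 and 174. In the same nuclei Kcnb2 was 4.63-fold, Plekhg3 2.90-fold and Synrg 2.87-fold lower. Thinned, the log2 ratio of Kcnb2 went from -1.95 to -0.71, of Plekhg3 from -1.38 to -2.63, of Chia1 from 4.12 to 3.40 and of Jchain from 3.19 to 2.46. Without the 50 most abundant genes Chia1 came to 4.90, and Dcpp1 went from 3.99 to 4.77.

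The comparison of the tamsulosin library with control asks how far the treated model lies from the normal gland. In acinar-like nuclei Pnliprp1 lay at 45.6 CPM, Esp16 at 649 CPM and Arntl at 130 CPM with tamsulosin, but Lipo1 was higher than in scopolamine at 265 CPM. Cyp2a5 lay at 191 CPM in control, 32.8 in scopolamine and 81.4 in tamsulosin. Of the 29 lists, 12 lay above and 1 below the central range (12 and 0 thinned, 9 and 1 with lists matched on gene length too). The 1 below is the clock list, at percentile 60.4 thinned, and NF-kB came to percentile 93.4 with members of at least 100 UMIs and 97.2 without clusters 0, 19 and 22. Junctions came to 97.0 thinned and chemokines to 97.4 at Leiden resolution 2.0, and heat shock, at percentile 95.8, went above the range under 4 settings (98.05 to 99.8). Matched on gene length too, androgen response came to percentile 87.2, the mitochondrially encoded list to 82.3 and the unfolded protein response to 92.8. The tear and secretory list had 17 of 20 members higher (relative median 1.75), ribosomal protein genes 24 of 26 (1.245), interferon response 11 of 21 (0.59) and the unfolded protein response 9 of 24 higher and 3 lower (0.29). Before the shift the last median was -0.05, and it changed sign under both other scalings. As plain CPM ratios with an interval beyond 1, 6 unfolded protein response genes were at least 1.5-fold higher and 6 lower. In fibroblast-like nuclei 18 of 21 matrix genes were higher (1.44), but with at least 1000 UMIs and 500 genes that list was at percentile 90.2. In acinar-like nuclei the relative medians of markers of other cell types were 0.28 for 11 fibroblast and -0.14 for 7 myoepithelial markers. They were 0.26 for 10 endothelial, 0.20 for 13 macrophage and 0.26 for 8 T or NK markers. These medians lie closer to 0 than the subtracted class median of -0.33, so the medians above 0 do not show higher plain levels. At least 1.5-fold higher were 0, 0, 0, 3 and 0 of the markers, and 1 endothelial and 1 macrophage marker was lower.

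The median absolute log2 ratio in acinar-like nuclei was 0.31 (0.30 to 0.31) between scopolamine and control, 0.14 (0.13 to 0.14) between tamsulosin and scopolamine and 0.38 (0.38 to 0.39) between tamsulosin and control. Counting noise alone gave 0.03, 0.04 and 0.03. After the median shift was taken out the distances were 0.20, 0.10 and 0.20, and the last pair of libraries lay 0.21 apart with totals without the 50 most abundant genes. On a scale with control at 0 and scopolamine at 1, the tamsulosin library lay at 1.03 in acinar-like nuclei (1.01 to 1.07 over 20 divisions, 215 genes). Both distances are taken from the same control library, so a difference particular to that library puts the position near 1 whatever tamsulosin does. The position was 1.18 in duct- (1.05 to 1.245), 1.38 in myoepithelial- (1.12 to 1.65), 1.26 in fibroblast- (1.14 to 1.47), 1.16 in macrophage- (1.02 to 1.29) and 0.90 in T or NK-like nuclei (0.73 to 1.01). Genes higher in scopolamine gave 0.97, 1.15, 1.06, 0.95 and 0.80 and genes lower in it 1.36, 1.46, 1.41, 1.23 and 0.93. The class medians of tamsulosin against control were -0.37, -0.66, -0.47, -0.40 and -0.46 log2 units in the same order.

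Of the alpha-1 adrenergic receptor genes, Adra1a (ENSMUSG00000045875, chromosome 14, 66635251 to 66771168) was measured in acinar-like nuclei at 323, 193 and 162 CPM in control, scopolamine and tamsulosin. In nuclei thinned to 1000 UMIs, with 673 shallower scopolamine acinar-like nuclei left out, 23.8, 12.5 and 12% of acinar-like nuclei had an Adra1a UMI, against 15.2, 6.48 and 3.05% of macrophage-like nuclei. Fibroblast-like nuclei had 18.8, 8.61 and 3.68% and T or NK-like nuclei 26.2, 5.29 and 0.952%. In control the T or NK-like share, over 107 nuclei, was thus above the acinar-like share. Chrm3 (ENSMUSG00000046159, chromosome 13, 9875486 to 10360847), the muscarinic receptor gene of exocrine glands, lay at 3750, 3696 and 3336 CPM. A Chrm3 UMI was seen in 97.0, 92.3 and 89.7% of thinned acinar-like nuclei and in 90.8, 65.7 and 34.2% of macrophage-like nuclei, a background that differed between libraries. Median depths before thinning were 2131, 1264 and 4527 UMIs in acinar-like and 2358.5, 1861.5 and 2619 in macrophage-like nuclei. Adra1b had 5, 5 and 1 UMIs and Adra1d 1 UMI in each library among acinar-like nuclei, and Vipr1, a receptor for vasoactive intestinal peptide, lay at 17.3, 15.1 and 17.2 CPM.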

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

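Of the tests in this part, the comparison of secretory transcript composition was written down before its result was seen, and all others were chosen afterwards.

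Salivary-type nuclei, a class no comparison used, made up 1.91% (1.67 to 2.19) of the tamsulosin library, 0.546% of the control library and 0 of 9205 scopolamine nuclei, and were noted because the tamsulosin share lay above the control interval. Unnamed low-complexity nuclei were noted for the same reason, at 5.78% of the scopolamine and 29.9% of the tamsulosin library against 0.693% of control.

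Secretory transcripts took a larger share of UMIs in every compared class of the scopolamine and tamsulosin libraries than in control, as in macrophage-like nuclei at 2.91, 6.39 and 9.83% for the tear list. In myoepithelial-, fibroblast-, macrophage- and T or NK-like nuclei of these libraries at most 4.82% (4.61% without the myoepithelial-like class) of the secretory UMIs would have to change gene to match acinar-like nuclei of the same library, which is consistent with free RNA spread over all droplets. Whether more cytoplasmic RNA of every kind played a part stays open for scopolamine against control. In fibroblast-, macrophage- and T or NK-like nuclei together the share of the tear list with Mucl2, Scgb2b2 and Scgb1b2 was 2.97-fold higher. The ribosomal share was 1.2497-fold higher, a ratio of 2.37. Nuclei of these classes also make ribosomal protein transcripts, which can hold the ribosomal fold down, so this ratio decides nothing. With the tear list alone the ratio was 1.87, and 1.38 in T or NK-like nuclei, the lowest of the 3 classes. For tamsulosin against scopolamine the ratio with Mucl2, Scgb2b2 and Scgb1b2 was 0.729, with folds of 1.57 and 2.16. The ribosomal share gained more than the secretory share, not by the same factor as this explanation predicts. These nuclei make ribosomal protein transcripts themselves, so the ratio decides nothing there either, and the question stays open. Whether acinar cells also made more of these transcripts, a difference the treatment could bring, stays open and untested.

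The duct-like share was 7.29% in the scopolamine and 31.6% in the tamsulosin library. The different UMI minimums of the libraries are argued against as the whole cause, since the ratio of shares was 2.70 with at least 1600 UMIs everywhere. Whether acinar nuclei left in the low-complexity clusters play a part cannot be told apart: the ratio was 4.20 among acinar-like, duct-like and low-complexity nuclei together, but these nuclei count in the share under either name, so this value decides nothing. Tissue of another gland in the sample cannot be told apart from a change in the gland: salivary-type nuclei came to 6.07% of the duct-like nuclei of the tamsulosin library, and the share of duct nuclei such tissue would bring is not known. An effect of tamsulosin was not testable with 1 library.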

How the results depend on the processing

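The settings without acinar-like clusters 0, 19 and 22 (the Kit and Car6 clusters), with at least 1600 UMIs, low-complexity clusters counted as acinar-like and random lists matched on gene length were chosen after the data were seen. Of 132 alternative values of class shares, distances, positions and list counts, 70 stayed within the interval or within 1.5 times the count, and 62 moved. Of 954 alternative list medians 595 stayed, 338 moved and 21 changed sign, and of 776 alternative ratios of named genes 586 stayed, 186 moved and 4 changed sign. The 595 include 96 from random lists matched on gene length, a setting that cannot change a median. These medians are taken before the class median is subtracted, so another scaling shifts every list. The counts therefore do not measure how stable the relative medians are. With at least 1000 UMIs and 500 genes acinar- and duct-like nuclei could not be compared, and at Leiden resolution 2.0 duct-like nuclei could not. No paired analysis was possible because each group has 1 library. Depth limits genes near the floor, 0.118 to 0.193 CPM in acinar-like and up to 10.1 CPM in T or NK-like nuclei. Except where the setting itself shows it, the cause was not tested.

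Shares are in percent and in the order control, scopolamine, tamsulosin where 3 are given. With doublets kept, acinar-like shares were 75.2, 65.0 and 22.5, duct-like 6.96, 8.32 and 33.2, and macrophage-like 6.996 in scopolamine and 5.04 in tamsulosin. With at least 1000 UMIs and 500 genes, acinar-like shares were 83.0, 64.0 and 45.6 (25.6 for tamsulosin without 1 cluster of 1927 nuclei with more top markers of another class), duct-like 0.457, 8.60 and 35.7, and macrophage-like 7.25 in scopolamine and 4.75 in tamsulosin. With genes centred within each library, acinar-like shares were 74.9, 65.7 and 24.3, and macrophage-like 5.28 in control. With at least 1600 UMIs, acinar-like shares were 75.78, 53.1 and 25.1 and duct-like 7.35, 12.2 and 33.0. At Leiden resolution 0.5 acinar-like shares were 66.5 in scopolamine and 20.1 in tamsulosin, and at 2.0 the tamsulosin acinar-like share was 24.6 and the control duct-like share 6.49. With low-complexity clusters as acinar-like, that share was 73.4 in scopolamine and 51.5 in tamsulosin.

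Distances in acinar-like nuclei follow for scopolamine and control, tamsulosin and scopolamine, and tamsulosin and control. They were 0.253, 0.105 and 0.235 with median-of-ratios scaling, 0.204, 0.109 and 0.212 without the 50 most abundant genes, 0.405, 0.164 and 0.461 thinned to 1000 UMIs, and 0.328, 0.147 and 0.409 with a pseudocount of 1. They were 0.350, 0.147 and 0.451 with doublets kept, 0.296, 0.149 and 0.393 at Leiden resolution 2.0, 0.283, 0.133 and 0.343 from 5 CPM, and 0.310, 0.144 and 0.40 from 50 CPM. With at least 1600 UMIs the first pair gave 0.237 and the second 0.202, and without the Kit and Car6 clusters the second gave 0.115 and the third 0.339. The position of the tamsulosin library was 1.07 without the 50 most abundant genes and 0.986 with at least 1600 UMIs.

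Over all settings 72 list medians crossed the central range of random lists. List medians below are log2 ratios before the class median is subtracted. For scopolamine against control with at least 1600 UMIs, mitochondrially encoded genes came to -0.43 (0.49 as reported) and ribosomal protein genes to -0.040 (0.43). Thinned to 1000 UMIs, apoptosis genes came to -0.053 (0.17), glucocorticoid genes to -0.026 (0.19) and junction genes to -0.091 (0.01). With members of at least 100 UMIs these came to -0.035, -0.079 and -0.067, and at Leiden resolution 2.0 junction genes to -0.011, and without the Kit and Car6 clusters to -0.021. Matrix genes in fibroblast-like nuclei came to -0.25 with at least 1000 UMIs and 500 genes. For tamsulosin against scopolamine, androgen response (0.03) came to -0.11 thinned and to -0.0022 with doublets kept. For tamsulosin against control, the unfolded protein response (-0.05) came to 0.14 with median-of-ratios scaling, 0.24 without the 50 most abundant genes, 0.14 thinned, 0.027 with members of at least 100 UMIs and 0.014 without the Kit and Car6 clusters. There, junction genes (-0.01) came to 0.092 with median-of-ratios scaling and 0.19 without the 50 most abundant genes, and NF-kB genes (0.16) to -0.0064 with members of at least 100 UMIs. Of the named genes, 31 had ratios that moved by more than 1.5 times under at least 1 setting, in 51 values, the pseudocount of 1 aside. The Trpm6 log2 ratio in myoepithelial-like nuclei, tamsulosin against scopolamine, came to 0.17 with doublets kept, and that of Dgkb in fibroblast-like nuclei, scopolamine against control, to -0.0023 with at least 1000 UMIs and 500 genes. Without the Kit and Car6 clusters the acinar-like log2 ratios of tamsulosin against scopolamine went from 0.90 to -0.24 for Nrg1, from 0.67 to -0.19 for Car6 and from 1.15 to 0.41 for Mup4.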

Other observations

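The tests of the clock pattern in this part, and the choice of the pattern, all came after the result was seen.

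B or plasma-like nuclei, the antibody lineage, made up 0.782% of control, 0.750% of scopolamine and 1.60% (1.37 to 1.86) of tamsulosin nuclei, or 5.19, 3.92 and 11.03% of the nuclei of 7 classes (myoepithelial-, fibroblast-, endothelial-, macrophage-, dendritic-, T or NK- and B or plasma-like). Endothelial-like nuclei were 0.634, 1.499 and 0.865% of all nuclei and 4.21, 7.84 and 5.96% of those 7 classes. Macrophage-like nuclei made up 30.9, 33.4 and 29.1% of the latter. Dendritic-like nuclei numbered 9, 19 and 15, and erythroid-like nuclei 14, 21 and 53. Apart from the macrophage-like class, these had under 100 nuclei in at least 1 library, so their genes were not compared. Xist, the transcript of the inactive X chromosome, lay at 1339, 1205 and 992 CPM over all nuclei, and the Y-linked Ddx3y had 1, 4 and 4 UMIs.

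For tamsulosin against scopolamine the log2 ratios were lower in longer genes in all 6 classes. Acinar-like genes had a median of 0.02 among the shortest 1145 genes and -0.17 among the longest, and macrophage-like genes -0.03 and -0.36. The ribosomal RNA-related transcript Gm42418 took 1.35, 0.301 and 0.266% of UMIs.

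Clock genes differed between control and the other 2 libraries in every compared class, and tamsulosin and scopolamine were close in acinar-like nuclei. Scaling by a few abundant genes is argued against: with median-of-ratios scaling the smaller of the median rise of Arntl and Npas2 and the median fall of Nr1d2, Tef and Per3 was 1.35 log2 units in acinar-like nuclei. In duct-, myoepithelial- and fibroblast-like nuclei 4 of 4 of Npas2, Per3, Dbp and Nr1d1 were above their acinar-like level in each class. For these genes this argues against free RNA from acinar-like nuclei as the whole source there. Free RNA from other classes was not tested. The 4 were picked after these levels had been seen, because they lay above, so the count of 4 of 4 was set by the choice. For Arntl, Nr1d2 and Tef in these classes free RNA cannot be told apart, since the smallest count was 0 of 3, and Arntl and Nr1d2 were above the acinar-like level in none of the 3. The same holds in macrophage- and T or NK-like nuclei, where the smaller count was 0 of 7. Collection at another time of day may account for the pattern, since Arntl and Npas2 were higher and Nr1d2, Tef and Per3 lower in 6 of 6 classes, and cannot be told apart from a systemic effect of the treatment, which predicts the same. The labels give no collection time, so the biological explanation stays untested.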
